A study of Homo sapiens with 12 samples.

How the data were processed

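Back-splice junction reads of circRNAs were measured by RNA sequencing in 12 libraries of the human glioblastoma cell lines LN229 and T98G, with 3 libraries in each of 4 groups (2 lines, each in normoxia and hypoxia). Per the labels' protocols, normoxic cells were kept in 95% air and 5% CO2 and hypoxic cells in 1% O2 and 5% CO2. RNA was extracted with TRIzol and ribosomal RNA was removed with Ribo-Zero. No digestion of linear RNA is named in the labels' protocols, and the duration of hypoxia is not given in the sources used here.

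The deposited table gives, for each circRNA and library, a whole-number count of junction reads and a log2 value, beside the position, strand, class, host gene and circBase identifier. The submitters' processing notes name CASAVA 1.8, BWA and the hg19 build, without their roles, and the tool that called circRNAs and its filters are not given in the sources used here. Coordinates are printed as the table gives them, and the reference genome at hand is of another build and was not used here. The table lists 12538 circRNAs. A further line was empty and not used here, and 3012 circRNAs had no read in any library. Of the 9526 with a read, 2150 are listed in neither circBase nor the publications the table cites, 10 carried no host gene and 98 a placeholder, and all stayed in the library totals, since a circRNA is identified by its position. All count columns matched a library by its title. The deposited log2 values were checked against the counts: in each library, 2 to the power of the value was a straight line in the count, with effective library sizes of 5914 to 6535 reads and a value of 5.30 at a count of 0. Their scaling method is not given in the sources used here, and they served only as an alternative scaling.

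Tests used the deposited counts in edgeR 4.0.16 under R 4.3.3, with limma 3.58.1. A circRNA was tested with at least 5 reads in at least 3 of the 12 libraries, which left 244 of 205 hosts. Library sizes were the total junction reads, 4298 to 7608, scaled by TMM, and 1 fit over all libraries held a mean per group. The quasi-likelihood F test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.261, a coefficient of variation of 0.511 between libraries of a group. CPM are TMM-scaled and relative to all junction reads, not to all RNA, so 1 read is worth 146 to 203 CPM. Means are given with SD and log2 fold changes with SE. Hypoxia against normoxia was tested in LN229, in T98G and averaged over both lines, with the difference of the responses (T98G minus LN229) and of the lines in normoxia. A fold against a group at 0 is a bound, computed from the pooled CPM and a floor of 3 counts over the group; the fitted log2 fold change of such a circRNA depends on the prior count. Shares have 95% Wilson intervals, and a count of 0 allows 3 counts.

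The groups, tests, thresholds, gene lists, the rule for named circRNAs and most alternatives were fixed before the data were examined. The rule named up to 10 circRNAs per direction that passed and whose hypoxia libraries all lay on 1 side of all normoxia libraries (in both lines for the average), or else the 3 with the smallest p. It also named the 5 with the smallest p per direction for the difference of responses, 10 for the lines, the 10 most abundant, the listed circRNAs known by name, matched by circBase identifier, and 2 to 4 members of each host list. Labels do not say that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which can be technical.

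Host gene lists with at least 5 tested circRNAs were tested by camera with a preset correlation of 0.01, namely hypoxia response, cell cycle and mitosis, DNA replication and repair, chromatin regulators, extracellular matrix and adhesion, glioblastoma drivers and growth factor signalling, and TGF-beta, Wnt, Notch and Hippo signalling. Lists with fewer, namely glycolysis and glycogen, ubiquitin ligases, splicing factors, neuronal and glial genes, fibroblast markers, endothelial and immune markers, abundant linear RNA, and stress and autophagy, are given as reads per library. The steps were tested on simulated data modelled on LN229 hypoxia against normoxia, with 244 circRNAs and 20 simulations. At the trended dispersion of the fit (median 0.191, a smaller spread than the common 0.261), the test found 2.5% of 200 circRNAs changed 2-fold, 31.5% of those changed 4-fold and 63% of those changed 8-fold, and 2% of its calls were false. With a dispersion of 0.02 it found 16%, 62% and 82.5%, with 7% false. Each simulated circRNA was drawn independently around 1 mean, while in the real libraries many circRNAs vary together. The shares found and false therefore do not cover such shared spread. Camera called a raised list in 20 of 20 simulations and an unchanged list in 1 of 20. The simulated members were raised together, while each real list had members both higher and lower in hypoxia. The simulations therefore do not show how often camera would find a change in the real lists.

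Values per library were compared by two-sided exact permutation tests in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9. Each pair of libraries was compared by a binomial test per circRNA over 243 tested circRNAs without that of CYP24A1 (Benjamini-Hochberg, 0.05). Over all circRNAs, each of the 66 pairs differed beyond sampling noise, with a dispersion 1.20 to 1.55 times that of sampling (200 resamples, smallest z = 15.0), so no pair was taken as the same library sequenced again and n stayed at 3. Whether libraries were prepared from the same RNA was not tested. Where a host gene has more than 1 tested circRNA, a value given under its name is that of 1 loop and not of the gene.

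Replicate numbers are shared by the groups in the labels. For the comparison of the lines in normoxia, deviations of same-numbered libraries from their group means correlated at r = 0.426, 0.358 and 0.648, each library best with its own number. Replicates 1 and 2 were barely told apart: LN229 replicate 2 had r = 0.358 with T98G replicate 2 and 0.327 with T98G replicate 1. The likeness rests mainly on replicate 3 lying apart in both lines and does not show pairing. A block was tried for this reason, which comes from the data, not from the labels. A fit with a replicate block shared by the lines called 0 circRNAs, as did the fit without the block. Alternatives tried were RLE size factors or no TMM, no filter or filterByExpr, DESeq2 1.42.0, a replicate block, only the groups compared, reads summed per host gene, an unadjusted threshold, and leaving out each library in turn. After the data were seen, the deposited library sizes, the CYP24A1 circRNA left out, 2 settings without several libraries, the block shared by the lines, sums of same-numbered libraries of the lines, and thinning without the CYP24A1 circRNA were added.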

Results

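Circular RNAs (circRNAs), closed RNA loops recognised in sequencing by reads across a back-splice junction, were measured in LN229 and T98G, 2 established human glioblastoma cell lines. Each line was grown in normoxia or in hypoxia at 1% O2, and each of the 4 groups held 3 libraries. The 12 libraries together held 71526 junction reads. In LN229 normoxia the totals were 5662, 4773 and 7608 reads, and in LN229 hypoxia 6637, 6893 and 5639. In T98G normoxia they were 5201, 4298 and 6011, and in T98G hypoxia 6841, 5550 and 6413. At least 1 read was found for 9526 circRNAs of 4068 host genes, of which 1102 had a single read over all libraries. Exonic loops made up 7784 of the 9526, against 1102 sense overlapping, 612 intronic, 18 antisense and 10 intergenic ones, as classed in the deposited table. Of the 9526 circRNAs, 76.4% carried a circBase identifier. Enough reads for testing were found for 244 circRNAs of 205 hosts.

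The most abundant circRNA came from CYP24A1, the vitamin D 24-hydroxylase gene (hg19, chromosome 20, 52773708 to 52788209, minus strand, exonic, predicted length 1106 nt). It took 24.6% of the reads of LN229 normoxia replicate 3 (95% Wilson interval 23.6 to 25.6%), but 2 reads in each of LN229 normoxia replicates 1 and 2. LN229 hypoxia held 1494, 387 and 1 reads of it, T98G normoxia 0, 1 and 675, and T98G hypoxia 1327, 998 and 1369. The count of 0 in T98G normoxia replicate 1 allows a share of up to 0.0577%. Next in abundance were circRNAs of HIPK3, a homeodomain-interacting protein kinase, with 33 to 79 reads per library, of the CDR1 locus, known as a microRNA sponge, with 1 to 94, and of SPECC1, which encodes a cytospin, with 6 to 82. RARS, XPO1, MAN1A2, RBM33, PLOD2 and GUSBP1 completed the 10 most abundant. Of these 10, none passed the test in either line: the CYP24A1 log2 fold change was 0.09 (SE 2.92) in LN229 and 2.68 (SE 3.11) in T98G, and that of HIPK3 was 0.22 (SE 0.47) and 0.46 (SE 0.47). Intervals and floors cover counting error only.

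**Figure D1:**
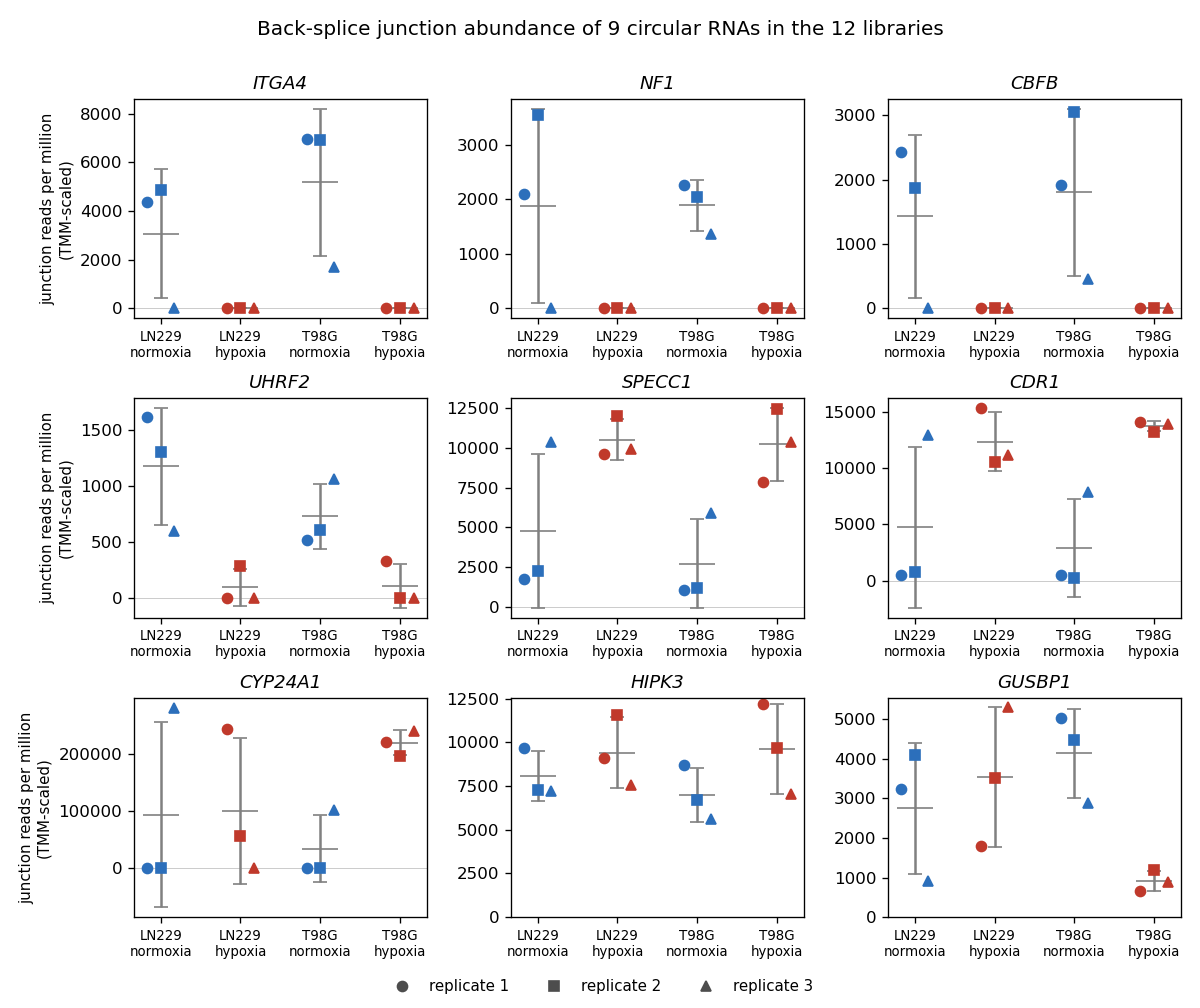
Abundance of 9 circRNAs in the 12 libraries, as TMM-scaled junction CPM (vertical axes, linear, 1 scale per panel), with groups on the horizontal axes. Points are libraries, with the marker showing the replicate and blue or red showing normoxia or hypoxia, grey bars are group means and error bars are SD (n = 3). The ITGA4 circRNA had 27, 26 and 0 reads in LN229 normoxia, 40, 34 and 11 in T98G normoxia and 0 in the 6 hypoxia libraries.

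Libraries of a group did not always resemble each other. LN229 normoxia replicate 3 correlated with replicates 1 and 2 at r = 0.0379 to 0.0488 across the 244 tested circRNAs (log2 CPM; circRNAs are not independent replicates), and differed from them in 25 and 28 of 243 circRNAs other than that of CYP24A1. With the 3 T98G hypoxia libraries it correlated at r = 0.691 to 0.748 and differed in 0 of 243. With the 3 LN229 hypoxia libraries it correlated at r = 0.227 to 0.725 and differed in 0 to 18. Closest of these was LN229 hypoxia replicate 1 (r = 0.725, 0 of 243 differing), which itself correlated with T98G hypoxia at r = 0.682 to 0.750. T98G normoxia replicate 3 correlated with its replicates 1 and 2 at r = 0.381 to 0.423 and with T98G hypoxia at r = 0.542 to 0.575. Within LN229 hypoxia, r ranged from 0.313 to 0.689. These libraries were kept in their labelled groups, and the counts without normoxia replicate 3 of both lines, a setting chosen after the data were seen, are given beside each count of called circRNAs. That setting leaves out normoxia libraries picked for lying apart from their group and near T98G hypoxia. More calls under it follow in part from the choice itself and are no evidence of a response to oxygen.

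**Figure D2:**
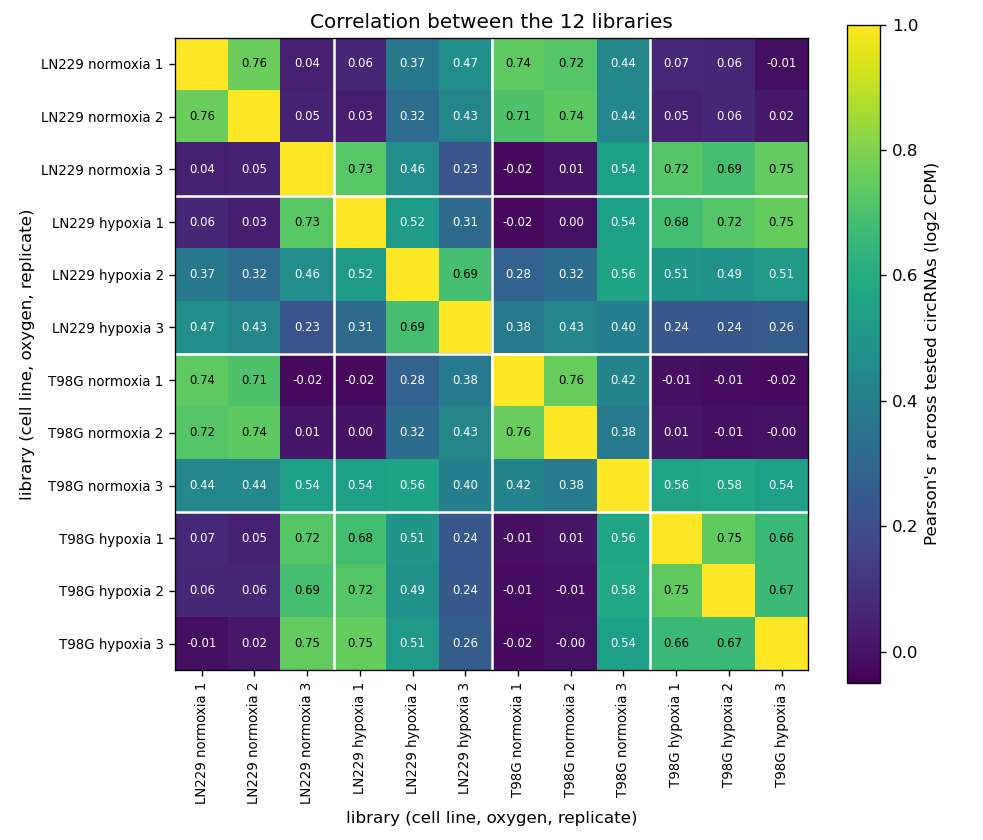
Pearson's r between each pair of the 12 libraries, across the 244 tested circRNAs on log2 CPM, with libraries on both axes named by line, oxygen and replicate. Normoxia replicates 1 and 2 of LN229 with those of T98G lie at r = 0.707 to 0.739. LN229 normoxia replicate 3 lies at r = 0.691 to 0.748 with T98G hypoxia and at r = 0.227 to 0.725 with LN229 hypoxia.

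The comparison within LN229 asked which circRNAs differ in abundance between hypoxia and normoxia in this line. The lowest p-values belonged to circRNAs of ITGA4, an integrin subunit of cell adhesion receptors, and NF1, which encodes the Ras regulator neurofibromin. ITGA4 had 27, 26 and 0 reads in normoxia and 0 in the 3 hypoxia libraries, and NF1 had 13, 19 and 0 against 0. Neither passed the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.095 for both), and against a floor of 3 counts over the hypoxia group they were at least 18.3-fold and 11-fold lower. ATRNL1 followed, with a log2 fold change of -4.20 (SE 1.12). On the higher side, 1 of 4 tested circRNAs of PTK2, focal adhesion kinase (chromosome 8, 141889570 to 141900868), stood at 329 ± 150 CPM in normoxia and 1410 ± 506 in hypoxia (SD, n = 3), while the other 3 had log2 fold changes of 0.64, -0.44 and -0.35. DCLK2, a doublecortin-like kinase, stood at 53.9 ± 93.4 against 1053 ± 252, and PVT1, a long non-coding RNA beside MYC, at 433 ± 149 against 1542 ± 647. None of PTK2, DCLK2 and PVT1 passed the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.204, 0.204 and 0.255).

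In LN229, 0 of 244 circRNAs passed an adjusted p of 0.05 by edgeR, 20 had an unadjusted p under 0.05 (6 higher and 14 lower), and DESeq2 called 0. In 24 circRNAs (9.8%) the hypoxia and normoxia libraries did not overlap, where chance gives 10%. Without LN229 normoxia replicate 3 the count was 15 (6 higher and 9 lower), and without normoxia replicate 3 of both lines it was 17 (7 higher and 10 lower).

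In T98G, the ITGA4 circRNA fell in hypoxia. It had 40, 34 and 11 reads in normoxia and 0 in all 3 hypoxia libraries, which is at least 27.5-fold lower against the floor of 3 counts over the group (log2 fold change -7.93, SE 1.62; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.045). This loop spans chromosome 2, 182339687 to 182350719, plus strand (hg19), is classed as exonic with a predicted length of 834 nt, and is not listed in circBase. On the higher side none passed: QSER1 stood at 545 ± 355 CPM in normoxia and 2432 ± 1074 in hypoxia, FAM13B at 1287 ± 384 against 3421 ± 1137, and PLA2G4A, the cytosolic phospholipase A2 gene, at 101 ± 175 against 1232 ± 686 (SD, n = 3). Their adjusted p-values were 0.0983, 0.119 and 0.119 (edgeR quasi-likelihood, Benjamini-Hochberg). The GUSBP1 circRNA, from a beta-glucuronidase pseudogene whose reads can be shared with near-identical copies, had a log2 fold change of -2.16 (SE 0.56) and an adjusted p of 0.066 (edgeR quasi-likelihood, Benjamini-Hochberg). ASXL1, a Polycomb-associated chromatin regulator, had -1.82 (SE 0.47) and the same adjusted p of 0.066 (edgeR quasi-likelihood, Benjamini-Hochberg), and its other tested loop -0.29.

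In T98G, 1 of 244 circRNAs passed and 51 had an unadjusted p under 0.05 (25 higher and 26 lower). In 90 circRNAs (36.9%, with 43 higher and 47 lower in hypoxia) the hypoxia and normoxia libraries did not overlap, where chance gives 10%. Many circRNAs vary together over the libraries, so 1 ordering of the libraries can separate many at once. The share was therefore not tested against 10%. The count of 1 became 0 with DESeq2, with RLE size factors, with the CYP24A1 circRNA left out and with reads summed per host gene. It also became 0 without any 1 of T98G normoxia replicates 1 and 2, T98G hypoxia replicates 1, 2 and 3, and LN229 hypoxia replicates 2 and 3. LN229 libraries can move the T98G count because all libraries share 1 estimate of spread. It became 16 without T98G normoxia replicate 3, 29 (13 higher and 16 lower) without LN229 normoxia replicate 3, 4 without LN229 hypoxia replicate 1, 36 with only the T98G libraries in the fit, and 48 (25 higher and 23 lower) without normoxia replicate 3 of both lines; the other settings are given with the processing alternatives.

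Averaged over both lines, 10 circRNAs fell in hypoxia and 0 rose. Those of ITGA4, NF1, CBFB, HLA-DRB1, ASCC2 and EZR had 0 reads in the 6 hypoxia libraries. CBFB encodes the beta subunit of core-binding factor, HLA-DRB1 a class II major histocompatibility chain, ASCC2 a subunit of an activating signal cointegrator complex, and EZR the membrane-actin linker ezrin. Against the floor of 3 counts over the group, NF1 was at least 11-fold lower in LN229 and 10.3-fold in T98G, CBFB 8.61-fold and 9.38-fold, HLA-DRB1 5.86-fold and 7.76-fold, ASCC2 4.13-fold and 5.5-fold, and EZR 3.10-fold and 5.82-fold. The remaining 4 were ATRNL1 (log2 fold change -3.96, SE 0.75), UHRF2, a chromatin-binding ubiquitin ligase (-2.85, SE 0.78), ARHGAP35 (-2.50, SE 0.68), and PMS1, a mismatch repair gene (-1.40, SE 0.39).

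In UHRF2 alone of these 10 did all hypoxia libraries lie below all normoxia libraries in both lines. The loop (chromosome 9, 6420912 to 6434173, plus strand, exonic) stood at 1174 ± 520 CPM in LN229 normoxia and 97.6 ± 169 in hypoxia, and at 732 ± 291 and 111 ± 193 in T98G (SD, n = 3). It had 10, 7 and 4 reads in LN229 normoxia and 0, 2 and 0 in hypoxia. In T98G it had 3, 3 and 7 against 2, 0 and 0, so the separation there is narrow. The other 9 fall outside the rule for named circRNAs and were named after their values were seen. In LN229 normoxia replicate 3, ITGA4, NF1, CBFB, HLA-DRB1, ASCC2 and EZR had 0 reads, and ATRNL1 had 1. Adjusted p-values were 0.00217 for ITGA4, 0.00331 for NF1 and for ATRNL1, 0.00577 for CBFB, 0.00969 for HLA-DRB1, 0.0294 for ASCC2, 0.0444 for EZR, ARHGAP35 and UHRF2, and 0.0449 for PMS1 (edgeR quasi-likelihood, Benjamini-Hochberg). The HLA-DRB1 loop spans 32487147 to 32548633 on chromosome 6, a stretch that holds paralogous genes, so its reads are uncertain.

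Among circRNAs higher on average, those with the smallest p did not pass. PTGR1, prostaglandin reductase, had 0, 0 and 2 reads in LN229 normoxia and 3, 5 and 6 in hypoxia, and in T98G 0 in the 3 normoxia libraries against 3, 2 and 5, with an adjusted p of 0.0641 (edgeR quasi-likelihood, Benjamini-Hochberg). SPECC1 had 11, 12 and 69 reads in LN229 normoxia against 59, 82 and 58, and 6, 6 and 39 in T98G normoxia against 47, 63 and 59, with an adjusted p of 0.0854 (edgeR quasi-likelihood, Benjamini-Hochberg). The microtubule crosslinker MTCL1 had a log2 fold change of 1.61 (SE 0.56). In all, 47 circRNAs had an unadjusted p under 0.05 (19 higher and 28 lower), and in 7 (2.9%) the groups did not overlap in both lines, where chance gives 0.5% for independent lines. Here too many circRNAs vary together, and the share was not tested against 0.5%. DESeq2 also called 10, of which 9 were shared, with PTGR1 higher and PMS1 no longer passing.

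Same-numbered normoxia libraries of the lines vary together, mainly through replicate 3. With same-numbered libraries of the lines summed, a setting chosen after the data were seen, 3 of the 10 passed, those of ITGA4, NF1 and ATRNL1. The count of 10 became 47 (23 higher and 24 lower) without LN229 normoxia replicate 3 and 17 without T98G normoxia replicate 3. It became 5 without LN229 normoxia replicate 1, LN229 normoxia replicate 2, T98G normoxia replicate 2, T98G hypoxia replicate 2 or T98G hypoxia replicate 3, 4 without T98G normoxia replicate 1, and 6 without LN229 hypoxia replicate 2 or 3. Without normoxia replicate 3 of both lines it was 56 (30 higher and 26 lower, all 10 included), and CDR1 (log2 fold change 4.71), SPECC1 (2.77) and MTCL1 (3.40) were then among those higher. Leaving out normoxia libraries that lie near hypoxia ones favours more calls by itself.

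Host gene lists fixed beforehand were compared with the other tested circRNAs in LN229, in T98G and on average, and camera called none of 7 lists in any of the 3. Camera's power for lists with members both higher and lower, as each of these had, was not tested. The absence of calls therefore does not show that the lists were unchanged. Adjusted p-values were at least 0.842 in LN229, 0.832 in T98G and 0.834 on average (camera, Benjamini-Hochberg), and no list was called with an estimated correlation, the smallest adjusted p then being 0.834, or without normoxia replicate 3 of both lines. By fry's mixed test, which asks whether members change in either direction without comparing them with other genes, chromatin regulators and extracellular matrix and adhesion genes passed in each contrast. For chromatin regulators the adjusted p was 0.000598, 0.00635 and 7.3e-05 in LN229, in T98G and on average, and for matrix and adhesion genes 0.0152, 0.0181 and 0.011 (fry mixed, Benjamini-Hochberg).

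Of 8 extracellular matrix and adhesion circRNAs, ITGA4 fell in T98G and on average. Adjusted over the list alone, 1 passed in T98G, 1 on average and 2 in LN229. Those in LN229 were ITGA4, which was lower, and 1 loop of PTK2, which was higher (log2 fold change 2.02, SE 0.65). VCAN, the proteoglycan versican, had a log2 fold change of 2.41 (SE 1.06) in T98G that did not pass. Of 10 circRNAs of chromatin regulators, UHRF2 fell on average. Adjusted over the list alone, 3 passed on average. UHRF2 and ASXL1 were lower (log2 fold change -2.85 and -1.01), and SFMBT2 was higher (2.37, SE 0.86). In LN229, 2 passed, UHRF2 (-3.24) and NCOA2 (-2.64), and in T98G 1, ASXL1 (-1.82), all lower. Of 5 circRNAs of glioblastoma drivers and growth factor signalling, NF1 fell on average. Adjusted over the list alone, NF1 passed in LN229, in T98G and on average, each time lower. PVT1 passed in LN229 and on average, each time higher (log2 fold change 1.77 and 1.28). Adjusted over the 8 tested circRNAs known by name, the same PVT1 loop did not pass (adjusted p = 0.109 in LN229 and 0.0506 on average, edgeR quasi-likelihood, Benjamini-Hochberg). Of 6 circRNAs of DNA replication and repair, PMS1 fell on average; adjusted over the list alone, it passed in T98G and on average, and 0 passed in LN229.

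Of 5 circRNAs of hypoxia response genes, 0 passed over all tested. They came from PLOD2, a collagen lysyl hydroxylase, ZNF292 and TET2, and adjusted over the list alone 1 passed, 1 of 2 loops of ZNF292 in T98G (log2 fold change -3.46, SE 1.13, against -0.77 for the other). PLOD2, with 10 to 33 reads per library for its more abundant loop, had log2 fold changes of 0.62 (SE 0.42) in LN229 and 0.05 (SE 0.44) in T98G. Of 6 circRNAs of cell cycle and mitosis genes, 5 were lower in each line, and of 7 of TGF-beta, Wnt, Notch and Hippo signalling genes, 4 were lower in each line; 0 passed in either list, over all tested or adjusted over the list alone. For matrix and adhesion, the median log2 fold change on average was 0.48 and the mean -0.54, and for glioblastoma drivers 0.45 and -0.75, both with camera's direction up. With ITGA4 and NF1 placed at their bounds, the medians were the same and the means were -0.16 and -0.14. For hypoxia response the median on average was 0.30 and the mean -0.28, with camera's direction down. Median and mean also differed in sign for matrix and adhesion in each line, for glioblastoma drivers in LN229, and in T98G only with the fitted value of NF1 (mean -0.38, and 0.24 with NF1 at its bound, beside a median of 0.79), for hypoxia response in T98G, and for TGF-beta, Wnt, Notch and Hippo on average. Camera's direction was up for this signalling list in LN229, where median and mean were below 0.

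Lists with fewer than 5 tested circRNAs are given as reads per library, for LN229 normoxia, LN229 hypoxia, T98G normoxia and T98G hypoxia in turn. Neuronal and glial genes, which include CDR1, had 33, 31 and 106 reads, then 114, 109 and 96, then 34, 30 and 80, then 105, 84 and 93. Of these, the CDR1 circRNA alone took 3, 4 and 86, then 94, 72 and 65, then 3, 1 and 52, then 84, 67 and 79. The higher values of this list are therefore those of CDR1 and not of its other genes. Glycolysis and glycogen genes had 10, 9 and 18, then 11, 27 and 19, then 23, 22 and 14, then 11, 13 and 13. Ubiquitin ligases had 193, 164 and 180, then 144, 246 and 205, then 152, 143 and 173, then 153, 132 and 151. Splicing factors had 103, 84 and 98, then 107, 133 and 107, then 100, 74 and 89, then 103, 70 and 93. Stress and autophagy genes had 39, 37 and 40, then 46, 80 and 57, then 32, 36 and 41, then 45, 45 and 44. Fibroblast markers had 3, 0 and 1, then 6, 5 and 4, then 5, 2 and 1, then 0, 0 and 3, and endothelial and immune markers 2 in LN229 normoxia replicate 1 and 0 in the other 11. Hosts of abundant linear RNA had 20, 18 and 4, then 10, 12 and 8, then 5, 3 and 11, then 2, 0 and 2. Only 2 of the 33 listed hosts had a read, and these are junction reads, not a measure of linear RNA. They were lower in hypoxia than in normoxia of T98G. In LN229 normoxia, replicate 3 was lower than replicates 1 and 2, while in T98G normoxia it was higher.

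Of 20 circRNAs known by name and listed beforehand by circBase identifier, 15 were matched and 8 had enough reads for testing. None passed in LN229, in T98G or on average, over all tested or adjusted over the list alone. CDR1 (hsa_circ_0001946) had 3, 4 and 86 reads in LN229 normoxia against 94, 72 and 65 in hypoxia, and 3, 1 and 52 in T98G normoxia against 84, 67 and 79. Its log2 fold change on average was 1.78 (SE 0.69), with an adjusted p of 0.173 over all tested and 0.0506 over the list alone (edgeR quasi-likelihood, Benjamini-Hochberg). On average PVT1 (hsa_circ_0001821) had 1.28 (SE 0.45) and FBXW7 (hsa_circ_0001451), from a ubiquitin ligase gene, -0.79 (SE 0.31). ARHGAP26 (hsa_circ_0074362) had 2.44 (SE 0.96) in T98G and 0.54 (SE 0.99) in LN229. With all libraries ZNF609, ZKSCAN1, SETD3 and HIPK3 lay between -0.66 and 0.46 in both lines, but leaving out 1 library moved ZNF609 in T98G between -0.17 and 1.56, and changed the sign of ZNF609 (-0.04 to 0.21) and SETD3 (-0.17 to 0.57) in LN229. Without normoxia replicate 3 of both lines CDR1 passed over all tested in each line (log2 fold change 4.29 in LN229 and 5.12 in T98G), and on average CDR1, PVT1 and FBXW7 passed. Adjusted over the list alone, PVT1 then also passed in LN229, ZNF609 (1.55, SE 0.64), FBXW7, PVT1 and ARHGAP26 in T98G, and ARHGAP26 on average. These passes follow in part from leaving out the normoxia libraries that lie near hypoxia ones.

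Whether the hypoxia response differed between the lines was tested as the T98G effect minus the LN229 effect. GUSBP1 had the smallest p on the lower side: it stood at 2746 ± 1654 CPM in LN229 normoxia and 3538 ± 1759 in hypoxia, and at 4133 ± 1115 and 910 ± 258 in T98G (SD, n = 3). CAMSAP1, which binds microtubule minus ends, had -1.75 (SE 0.61), the transcriptional repressor BACH1 -2.82 (SE 0.99), ZBTB44 -2.47 (SE 0.87) and ASXL1 -1.62 (SE 0.65). On the other side stood AKAP12, a protein kinase A anchor, at 5.16 (SE 1.63), the nuclear receptor coactivator NCOA2 at 3.74 (SE 1.27), PLA2G4A at 4.19 (SE 1.5), FAM13B at 1.58 (SE 0.62) and ATXN2 at 3.01 (SE 1.26). None passed: edgeR called 0 of 244 (smallest adjusted p = 0.401, quasi-likelihood, Benjamini-Hochberg), 19 had an unadjusted p under 0.05, and DESeq2 called 0. Without normoxia replicate 3 of both lines 1 was called, GUSBP1 (log2 difference -2.33). Without LN229 normoxia replicate 3, whose 18 AKAP12 reads stood beside 0 in replicates 1 and 2, the AKAP12 difference was -0.35.

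The lines were also compared in normoxia, as T98G minus LN229. ZBTB44 was higher in T98G at 1659 ± 531 CPM against 636 ± 405 (SD, n = 3), while NCOA2, the matrix proteoglycan gene VCAN and a mitochondrial loop annotated to OK/SW-cl.16 were lower, with log2 differences of -1.84 (SE 0.84), -2.31 (SE 1.06) and -2.05 (SE 0.97). None of them passed: edgeR called 0 of 244 (smallest adjusted p = 0.984, quasi-likelihood, Benjamini-Hochberg), these 4 were the ones with an unadjusted p under 0.05, and DESeq2 called 0. Next by p on the higher side came BACH1, DCBLD2, RBM39, FANCL, KMT2C, ARHGAP5, ERC1, PPP4R1 and CAMSAP1, with log2 differences from 0.64 to 1.69, and on the lower side FAM13B, ATXN2, CDYL, CSNK1G3, FAT3 and MAN1A2, from -1.89 to -0.66. An AKR1E2 loop, of an aldo-keto reductase gene (chromosome 10, 4872867 to 4889491), had 0, 0 and 7 reads in LN229 normoxia and 0 in T98G normoxia, at least 2.21-fold lower against the floor of 3 counts over the group, with all its reads in LN229 normoxia replicate 3. AKR1E2, OK/SW-cl.16 and ARHGAP5 each have a second tested loop, with log2 differences of 0.06, 0.36 and -1.09. FANCL and MAN1A2 also have further tested loops, whose differences are not given here. In 23 circRNAs (9.4%) the lines did not overlap, where chance gives 10%. Without normoxia replicate 3 of both lines 0 were called. Between normoxia replicates 1 and 2 of LN229 and those of T98G, 0 of 243 circRNAs differed in any of the 4 pairs. The FAT3 difference of -1.89 was 0.35 without LN229 normoxia replicate 3.

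The responses of the lines were set side by side. No circRNA was called in both. With 0 called in LN229 no overlap was possible, so this count does not test whether the responses are shared. Across the 244 circRNAs the log2 fold changes of LN229 and T98G correlated at r = 0.568 (rank correlation 0.304), and at r = 0.259 (rank correlation -0.000324) without LN229 hypoxia replicate 1; circRNAs are not independent replicates. Same-numbered normoxia libraries of the lines vary together, mainly through replicate 3, so the 2 lists are not independent. More overlap than expected is therefore no evidence of a shared response. Without LN229 normoxia replicate 3, 11 circRNAs were called in both lines, all in the same direction, where independent lists would share 0.32 higher and 0.59 lower. Without normoxia replicate 3 of both lines these were 15, with 0.717 higher and 0.943 lower expected, ITGA4, CDR1, SPECC1 and NF1 among them, and r was 0.799. Both settings leave out normoxia libraries that lie near T98G hypoxia, which by itself favours calls and overlap.

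Detection and read classes per library were compared last. Circular RNAs with at least 2 reads numbered 1210 ± 122 in LN229 normoxia and 1291 ± 170 in hypoxia, and 1106 ± 142 and 1140 ± 159 in T98G (SD, n = 3). The differences of 81 and 34 had p = 0.5 and 0.9 (two-sided exact permutation test, for which 3 against 3 libraries cannot go below 0.1). Total reads were 6014 ± 1450 and 6390 ± 663 in LN229 and 5170 ± 857 and 6268 ± 658 in T98G, with exact permutation p = 0.8 and 0.2. Antisense loops, the class of the CDR1 circRNA, took 0.459 ± 0.593% of reads in LN229 normoxia and 1.27 ± 0.15% in hypoxia, and 0.44 ± 0.412% and 1.27 ± 0.0407% in T98G (exact permutation p = 0.2 and 0.1). In LN229 they had 5, 7 and 87 reads in normoxia and 95, 78 and 71 in hypoxia. CDR1 held 3, 4 and 86, then 94, 72 and 65 of these. In T98G they had 9, 10 and 55, then 85, 73 and 80, of which CDR1 held 3, 1 and 52, then 84, 67 and 79. The higher antisense share in hypoxia is therefore that of CDR1 and not of the class. The 10 most abundant circRNAs took 12.4 ± 14.2% and 14.7 ± 11.4% in LN229 and 8.03 ± 6.71% and 24.2 ± 1.4% in T98G (exact permutation p = 0.8 and 0.1). Most of this is the CYP24A1 circRNA. Without it the share was 4.05, 4.17 and 5.61% in LN229 normoxia and 6.30, 5.90 and 5.43% in hypoxia. In T98G it was then 4.10, 4.19 and 5.12% in normoxia and 5.55, 6.04 and 5.51% in hypoxia. Between the lines, 6 libraries against 6, totals differed by -483 reads and detected circRNAs by -128 (T98G minus LN229; exact permutation p = 0.405 and 0.136). All 24 tests of this family had a Benjamini-Hochberg adjusted p of at least 0.533 (exact permutation tests). Exonic reads took 86.1 to 89.4% of every library. Thinned to 4298 reads per library, detected circRNAs were 836 ± 167 in LN229 normoxia and 806 ± 145 in hypoxia, and 886 ± 89.6 and 713 ± 31.4 in T98G. The CYP24A1 circRNA still takes part of these reads. Thinned without it to 4297 reads, detected circRNAs were 923 ± 19.2 and 906 ± 34.7 in LN229 and 927 ± 17.4 and 934 ± 27.6 in T98G. Without normoxia replicate 3 of both lines the differences were 115 in LN229 and 77 in T98G for detected circRNAs, and 1172 and 1518.5 for totals.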

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

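Tests added after the result was seen are those with the deposited library sizes, with the CYP24A1 circRNA left out, without normoxia replicate 3 of both lines, without these and LN229 hypoxia replicates 1 and 2, with a block shared by the lines, with same-numbered libraries of the lines summed, and with thinning without the CYP24A1 circRNA. Of 1522 recomputed log2 fold changes of 84 named results, 1338 kept direction and side of the threshold, 81 newly passed, 72 no longer passed and 31, of 11 results, reversed. Of the counts and differences, 76 kept to within 1.5 times, or kept direction and side of the threshold, under other settings, 38 moved and 5 reversed. Where no cause is given below, the cause was not tested. The pseudocount alternative is for normalized units and was not run, and for the average and the difference of responses all groups are compared already. AKR1E2 between lines has no value without LN229 normoxia replicate 3, where all its reads lie. Leaving out normoxia replicate 3 of both lines and LN229 hypoxia replicates 1 and 2 leaves 1 LN229 hypoxia library, which is assumed to vary like the other groups. With 4298 to 7608 junction reads per library, simulated 2-fold changes were found in 2.5% of cases.

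The LN229 count of 0 circRNAs (20 at an unadjusted p under 0.05 by edgeR, 0 by DESeq2) was 5 with no filter on low counts, 17 without normoxia replicate 3 of both lines, 9 without these and LN229 hypoxia replicates 1 and 2, 19 at an unadjusted p under 0.05 and at least 2-fold, and 0 to 15 leaving out 1 LN229 library. The T98G count of 1 was 0 with RLE size factors, with CYP24A1 left out, with reads summed per host gene and with DESeq2, 8 without TMM, 9 with no filter, 4 with filterByExpr and with the deposited sizes, 48 and 66 without those 2 and 4 libraries, 36 with only the T98G groups, 51 unadjusted and 2-fold, and 0 to 16 leaving out 1 T98G library. The average count of 10 was 6 with RLE, 20 with no filter, 3 with filterByExpr, 56 and 41 without the 2 and 4 libraries, 16 with host sums, 40 unadjusted and 2-fold, 3 with same-numbered libraries of the lines summed, and 4 to 47 leaving out 1 library; it was 12 without TMM and 10 with the deposited sizes and with CYP24A1 left out.

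The difference of responses (0 by edgeR and DESeq2, 19 unadjusted) was 1 with no filter, 1 and 12 without the 2 and 4 libraries, 19 unadjusted and 2-fold, and 0 leaving out each library. The comparison of lines (0 by edgeR and DESeq2, 4 unadjusted by edgeR) was 4 unadjusted and 2-fold. Host lists called were 0 leaving out each library, and 2 with fry's mixed test in LN229, in T98G and on average. The overlap of 0 was 5 with no filter, 15 and 8 without the 2 and 4 libraries, and 0 to 11 leaving out 1 library.

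A replicate block gave 3 circRNAs in LN229, 3 in T98G, 3 in their overlap and 8 on average. The numbers do not pair the libraries of the hypoxia contrasts: not every library correlated best with its own number, and same-numbered libraries correlated at r = -0.44, 0.0892 and -0.518 in LN229.

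Without TMM the median log2 fold change of all tested circRNAs was -0.34 in T98G (-0.02 with TMM), -0.16 on average (0.04) and -0.21 for the difference of responses (0.03), which RLE put at 0.15 and DESeq2 at 0.16. The difference in detected circRNAs was -29.8 in LN229 and -173 in T98G when thinned to the smallest total, and -1 in T98G at 1 read. Thinned without the CYP24A1 circRNA it was -17.2 in LN229, 6.91 in T98G and 16.7 between lines, so that the T98G reversal rests on the share this circRNA takes. Leaving out 1 library it was 3.67 to 172 in LN229 and -52.5 (without T98G hypoxia replicate 1; -48 without T98G normoxia replicate 2) to 104 in T98G, and between lines -166 to -88.8. For totals the ranges were -245 (without LN229 normoxia replicate 2) to 1172, 662 to 1518.5, and -769 to -199.

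Reversed log2 fold changes in LN229 were those of CYP24A1 (-0.00938 with RLE, -0.0298 with filterByExpr, -0.0284 with the deposited sizes, -0.0093 with DESeq2, -0.88 without the 4 libraries, -1.73 to 8.09 leaving out 1), HIPK3 (-0.12 without the 4), ZNF609 (-0.13 without the 4, -0.041 to 0.21 leaving out 1), ARHGAP26 (-3.10 without the 4, -0.96 to 1.37 leaving out 1), GUSBP1 (-0.0512 without the 2, -0.0512 to 0.78 leaving out 1) and SETD3 (-0.0746 without the 2, -0.17 to 0.57 leaving out 1). In T98G they were MAN1A2 (-0.0015 without TMM), PLOD2 (-0.27 without TMM, -0.0122 with no filter, -0.0458 with the deposited sizes, -0.20 to 0.19 leaving out 1) and ZNF609 (-0.0736 without TMM, -0.17 to 1.56 leaving out 1). Leaving out 1 library, AKAP12 in the difference of responses ranged from -0.35 to 8.26 and FAT3 between lines from -3.01 to 0.35. None of these passed the test (edgeR) with all libraries.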

Other observations

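The tests of depth, of a label swap, of low oxygen, of the same cells behind both line names and of splits of summed libraries were chosen after the result was seen; the tests of a mixture, of host transcripts and of the remaining splits were written before. Some circRNAs had almost no reads in normoxia replicates 1 and 2 of both lines. FGD6 had 0, 0 and 25 reads in LN229 normoxia, 25, 9 and 2 in LN229 hypoxia, 0, 1 and 17 in T98G normoxia and 28, 24 and 25 in T98G hypoxia. MTUS1, a microtubule-associated tumour suppressor, had 0, 0 and 14, then 18, 10 and 2, then 0, 0 and 6, then 15, 16 and 14. PDE4D, a cyclic AMP phosphodiesterase, had 0, 0 and 16, then 14, 5 and 0, then 0, 0 and 7, then 8, 15 and 8. These 3 were chosen after their values were seen.

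Normoxia replicate 3 of both lines stands apart from normoxia replicates 1 and 2. Library depth and the share taken by the CYP24A1 circRNA are argued against: without it and at equal depth, each pair still differed in at least 5 circRNAs more than replicates 1 and 2 did. Equal depth was reached by 1 random thinning per pair, not repeated, so these counts hold the noise of 1 draw. At equal depth, a swap of labels with a hypoxia library within T98G is argued against (at least 11 circRNAs more than between replicates 1 and 2). Without thinning, T98G hypoxia libraries differed from T98G normoxia replicates 1 and 2 in 21 to 32. A swap within LN229 stays open, with values on both sides. At equal depth, LN229 hypoxia replicate 3 differed from LN229 normoxia replicates 1 and 2 in 4 each, and without thinning in 10 and 6. Exchanging it with LN229 normoxia replicate 3 gave 17 calls in LN229 and 51 on average. Yet LN229 hypoxia replicate 3 had 0 ITGA4 reads (27 and 26 in normoxia replicates 1 and 2) and 65 of CDR1 (3 and 4). It also differed from LN229 hypoxia replicate 2 in 0. For T98G normoxia replicate 3, a mixture with 42% of the replicate 1 and 2 profile and the rest of T98G hypoxia was fitted. It left a residual of 1.12 per degree of freedom, against 12.4 and 18 unmixed. RNA of other libraries is a candidate explanation there, as is a culture in an intermediate state. Low residuals of a mixture were not particular to this library. LN229 hypoxia replicate 2 as a mixture of LN229 hypoxia replicates 3 and 1 left 1.49, against 2.52 and 5.70 unmixed. T98G hypoxia replicate 1 as a mixture of T98G hypoxia replicates 2 and 3 left 1.35, against 1.77 and 2.13. The best mixture for LN229 normoxia replicate 3, with the 3 LN229 hypoxia libraries pooled, left 3.58.

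All 6 tested circRNAs with 0 reads in the 6 hypoxia libraries, those of ITGA4, NF1, CBFB, HLA-DRB1, ASCC2 and EZR, are among the 16 tested ones listed in neither circBase nor the publications the table cites, against 0 of the other 228; they vary together over the libraries, and this was seen after they were picked. Fewer host transcripts cannot be told apart from other causes: pooled over 16 other circRNAs of these hosts, hypoxia stood at 0.902 of normoxia in T98G (95% interval 0.408 to 1.97) and 1.03 in LN229 (0.478 to 2.24), on 14 to 16 reads per condition. Low oxygen stays open as well. In LN229 normoxia replicate 3, 85.2 reads of these junctions would be expected at the level of replicates 1 and 2 and 0 were found (up to 3.52%), and in T98G normoxia replicate 3, 33 of 106 were found (31.1%). Their absence therefore may go with whatever sets replicate 3 apart rather than with oxygen, which 1 library per line cannot decide.

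Normoxia replicates 1 and 2 of LN229 and T98G look alike, with 0 of 243 circRNAs differing in each of 4 pairs. Depth too low to see a difference stays open for all but large changes: LN229 normoxia replicates 1 and 3 differed in 25, but the smallest change among those with reads in both was 2.73-fold, that of XPO1, so their difference does not show that smaller ones would be seen. The same cells behind both line names cannot be told apart from a likeness of the lines: the lowest correlation between them was r = 0.707, and either gives this. No test of line identity from sequence was made here.

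Other splits of the libraries were also fitted. For the average over lines, 3 of 100 splits, the real one included, called at least its 10 circRNAs, so chance is excluded only if libraries of the 2 lines vary independently, and same-numbered normoxia libraries do not. The highest other split called 51. It exchanged LN229 normoxia replicate 3 with LN229 hypoxia replicate 3, the swap left open above. It therefore cannot tell oxygen from another structure of the libraries. With same-numbered libraries of the lines summed, 1 of 10 splits, the real one, called at least 3 (highest other 0), and 10 splits are too few for a share under 0.05. For T98G (1 of 10, real 1, highest other 0), 10 splits are also too few. For LN229 (10 of 10, highest other 17), the lines (10 of 10, highest other 3) and the difference of responses (100 of 100, highest other 51), the real count is 0, which each split reaches by definition, so the splits say nothing of chance there.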
